A study of Homo sapiens with 36 samples.

How the data were processed

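Neutrophils and lymphocytes were isolated from whole blood with immunomagnetic EasySep Direct kits, RNA was extracted with RNeasy Mini columns, and directional mRNA libraries were made with the TruSeq kit and sequenced on an Illumina NextSeq instrument, per the labels' protocols. The submitters' processing notes name STAR, a spliced aligner, Cufflinks and Cuffdiff, which quantify transcripts, and the hg38 genome build; their versions, order and settings and the annotation release are not given in the sources used here. The deposited table holds 1 value per gene and library, taken as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) computed by the authors. That unit was inferred from the tools named and from the values, since the file header does not state it, and whether Cuffdiff also scaled the libraries to each other is not given. Cuffdiff estimates can be listed as exactly 0 where an estimate fails, so a gene at 0 in whole groups is reported here as listed at 0, with library values and no fold.

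The table held 37247 genes, of which 80 sex-linked genes (Y chromosome, XIST and TSIX) were left out and 37167 kept. Of the gene identifiers, 36910 (99.1%) matched GENCODE release 29, which gave coordinates on hg38. No pair of libraries was identical. FPKM summed to means of 823916 to 875215 over the neutrophil groups and 385505 to 410876 over the lymphocyte groups. The noncoding RNAs RPPH1 and RMRP took a mean of 2.80%, 5.53% and 3.80% of FPKM in NLR-high, NLR-low and healthy neutrophils and 9.77%, 13.6% and 12.6% in the lymphocytes of those groups. Depth is not recorded in FPKM. An approximate relative depth was taken from the lowest values of 6481 single-exon genes, with an assumed fragment length of 200 bases, and is used as a description only.

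Groups were taken from the labels, with 6 libraries in each. Before the data were examined, the tests, the gene lists, the rule for named genes and the other settings to be tried were fixed. Within a cell type, all 3 donor groups (18 libraries) entered 1 limma fit on log2(FPKM + 0.5), with a trend of the variance on the mean. Genes with at least 1 FPKM in at least 6 libraries were kept, 12777 in neutrophils and 13965 in lymphocytes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes on this scale understate the changes of low genes. Interactions and the comparison of the cell types used all 36 libraries and 16073 genes. In all, 29 gene lists and 15 lists of cell type and RNA quality markers were drawn up, and those with at least 3 tested members were tested with camera (preset correlation 0.01), with an estimated correlation and with fry. With an estimated correlation none of the list calls held in any of the 6 comparisons between donor groups. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes. Marker list means were compared by exact two-sided permutation tests, for which 6 against 6 libraries allow a smallest p of 0.00216. Links between the cell types of a donor used 100000 permutations within groups.

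The rule for named genes took, per comparison, genes with an adjusted p under 0.05 and a mean of at least 2 FPKM, up to 10 with the largest change in each direction, and where fewer than 5 passed also the 5 with the smallest unadjusted p. To these it added up to 4 members of each list with the smallest unadjusted p, and every tested complement gene in neutrophils. The text names a subset of the genes this rule allows, chosen after their values were seen, and a few that it allows are not reported here. IGHV3-21, RN7SL4P and ATP5LP6 lie outside the rule, as do EEF1A1, NAMPT and NEAT1, and the complement genes C1QA, C1QB, C2 and CFB, which were not tested under the filter; all were chosen after their values were seen. RPS and RPL genes and the MHC class II genes have near-identical copies, and the authors' quantification may have divided reads between them.

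Replicate numbers pair the neutrophil and lymphocyte libraries of a donor, as the labels give both the same donor. Over all genes, deviations from the group means correlated best with the donor's own library in 18 of 18 donors, with r from 0.068 to 0.176 and a consensus correlation of 0.108. The other settings were other pseudocounts, no filter and a stricter one, median-ratio scaling, quantile normalization, array weights, fits of 2 groups alone, other thresholds, the replicate block and each library left out in turn. Added after seeing the data were fits without genes listed at 0 in a whole group, without genes at least 4 times higher in lymphocytes, and without libraries whose T cell, platelet or monocyte transcripts stood apart. The labels give no batch. The limma test was tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale: for NLR-high against NLR-low neutrophils, over 12777 genes, it recovered 63% and 89% of them, and for NLR-low against healthy lymphocytes, over 13965 genes, 86% and 95%. Unchanged genes made up 4.40% of the calls (7 genes) in the first of these simulations and 5.73% (11 genes) in the second. The genes were simulated independently of each other, so the simulation does not show how the test behaves where genes vary together. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.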

Results

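The series profiled polyadenylated RNA from blood neutrophils and lymphocytes of patients undergoing vascular surgery and of healthy donors. The patients had been divided by their neutrophil-to-lymphocyte ratio (NLR), a blood count ratio used as a marker of systemic inflammation: NLR-low patients lay below 3 and NLR-high patients at 3 or above. Each of the 3 donor groups held 6 donors, and each donor gave 1 neutrophil and 1 lymphocyte library, so 36 libraries formed 6 groups of 6. Every mean below is a mean ± SD of FPKM over the 6 libraries of a group, and every log2 difference is on the log2(FPKM + 0.5) scale with its standard error (SE). The limma and permutation p-values within a cell type rest on the spread between donors. Those of camera with its preset correlation take the genes of a list as nearly independent and do not measure that spread. The main fits over all 36 libraries take the 2 libraries of a donor as independent. The values are FPKM, so the read depth of a library is not recorded. The spacing of the lowest values gave an approximate relative depth, the inverse of that spacing, under an assumed fragment length. It was 7.73 to 17.8 in neutrophil libraries and 20.4 to 33.1 in lymphocyte libraries. Any scaling of the libraries to each other would move this measure as well. The median SE of a log2 difference was 0.20 in neutrophils and 0.13 in lymphocytes, which holds the spread between donors as well as that of the measurement.

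Neutrophils and lymphocytes of the same donors were compared first, as a check of the cell types. All 13 neutrophil markers tested were higher in neutrophils, with a median log2 difference of 8.98. All 12 T cell markers, 12 B cell markers, 7 plasma cell markers and 6 basophil and mast cell markers were higher in lymphocytes, with median log2 differences of -6.41, -2.25, -0.96 and -4.04. Of 12 NK cell markers 11 were higher in lymphocytes, and of 11 monocyte markers 9 were higher in neutrophils. The 13 mitochondrially encoded transcripts were all higher in lymphocytes, with a median of -1.15. Across 16073 genes, limma called 14638 at an adjusted p under 0.05, 6890 higher in neutrophils and 7748 higher in lymphocytes. The median of all genes was -0.17, or -0.23 after median-ratio scaling, and the marker differences stand relative to that shift.

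The comparison that the series title raises is that of NLR-high with NLR-low neutrophils. By camera, the ribosomal protein, antigen presentation, B cell, plasma cell, interferon and granule precursor lists were lower in NLR-high neutrophils. Few single genes passed the test over all genes. RPS19, a component of the small ribosomal subunit, fell from 191 ± 41.4 to 90.2 ± 14.6 FPKM (log2 difference -1.07, SE 0.15, limma adjusted p = 0.00591). TMPO, a protein of the inner nuclear membrane, fell from 11 ± 3.76 to 3.93 ± 0.79 FPKM (-1.32, SE 0.21, adjusted p = 0.0191). The immunoglobulin heavy chain segment IGHV3-21 fell from 13.8 ± 4.67 to 1.32 ± 0.90 FPKM (-3.06, SE 0.52, adjusted p = 0.0332). The IGHV3-21 call was lost without genes listed at 0 in a whole group (adjusted p = 0.0551) and without genes 4 times higher in lymphocytes (0.0517), and over the settings that kept all libraries or left out the doubted ones its adjusted p ranged from 0.00111 to 0.0700, that of RPS19 from 0.00433 to 0.0697 and that of TMPO from 0.00182 to 0.0697. RPS19 and TMPO are themselves among the genes at least 4 times higher in lymphocytes. The fit without such genes leaves them out, and 0 lower calls remained in it. On hg38, RPS19 lies on chromosome 19 at 41859918 to 41872926, TMPO on chromosome 12 at 98515512 to 98550379 and IGHV3-21 on chromosome 14 at 106235064 to 106235594.

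The other 2 genes called were ANKRD28, which encodes a regulatory subunit of protein phosphatase 6, and RN7SL4P, a pseudogene of the signal recognition particle RNA. Both were listed at 0 in all 30 libraries outside the NLR-high neutrophils. In the 6 NLR-high neutrophil libraries ANKRD28 ranged from 9.85 to 25.6 FPKM and RN7SL4P from 41.9 to 245 FPKM. RN7SL4P (chromosome 3, 15738515 to 15738809, plus strand) lies within the span of ANKRD28 (chromosome 3, 15667236 to 15859771, minus strand), so the pair is 1 locus rather than 2 independent observations. An exact 0 in this table is not always an absence. EEF1A1, a translation elongation factor used by every cell, was listed at 0 in all 18 lymphocyte libraries and ranged from 115 to 253 FPKM in neutrophils. NAMPT, an enzyme of NAD synthesis, and NEAT1, a nuclear long noncoding RNA, were listed at 0 in all 18 neutrophil libraries.

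**Figure D1:**
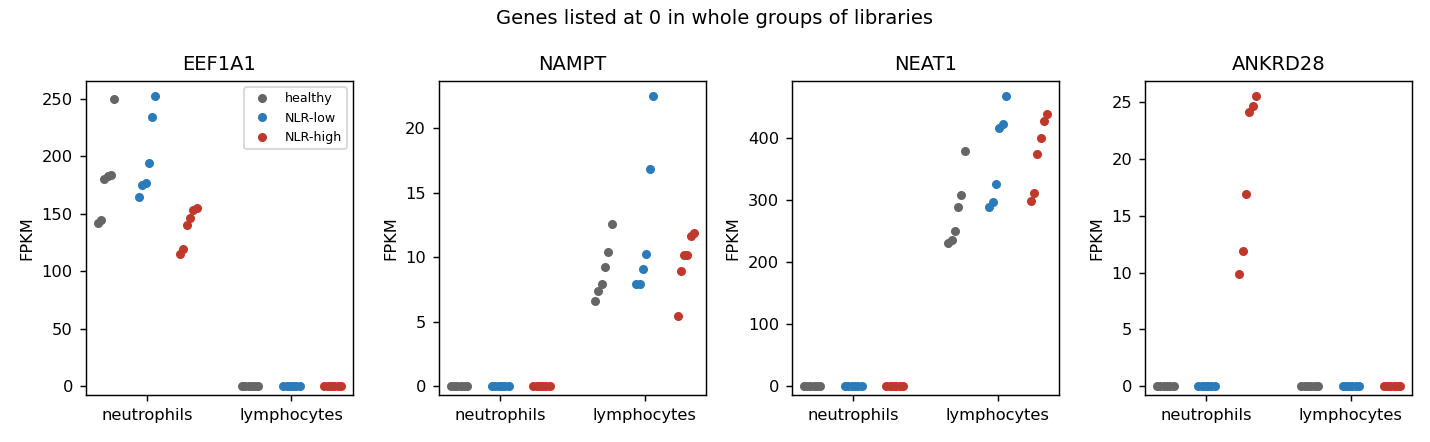
FPKM of EEF1A1, NAMPT, NEAT1 and ANKRD28 in each of the 36 libraries, 1 point per library, by cell type on the horizontal axis and donor group by colour. EEF1A1 is listed at 0 in all 18 lymphocyte libraries, NAMPT and NEAT1 in all 18 neutrophil libraries, and ANKRD28 in the 30 libraries other than the NLR-high neutrophils.

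Over the 12777 genes tested in neutrophils, limma called 5 genes between NLR-high and NLR-low, 2 higher and 3 lower (3 higher and 2 lower after quantile normalization). At an unadjusted p under 0.05 there were 2406 genes, or 18.8%, and the FPKM ranges of the groups did not overlap for 243 genes, or 1.90%, where chance gives 0.216%. Here and below, that share is the expectation for a single gene. Genes vary together, and the count was not regrouped, so its excess is a description only. NLR-low against healthy neutrophils, with 0 genes called, had 0.642%. The next genes by p were CC2D1A at 12 ± 0.94 against 7.76 ± 1.07, the zinc finger gene ZMYM2 at 55.9 ± 4.02 against 40.2 ± 5.27 and the pre-mRNA cleavage factor CPSF7 at 119 ± 17.3 against 78.5 ± 15.8 in NLR-high against NLR-low neutrophils. On the lower side stood the maintenance DNA methyltransferase DNMT1 at 4.59 ± 0.75 against 9.59 ± 2.20, the lipid droplet protein PLIN2 at 1.07 ± 0.51 against 3.38 ± 0.97 and the serine hydroxymethyltransferase SHMT2 at 1.19 ± 0.46 against 3.70 ± 0.89. The limma adjusted p of all 6 was 0.0540. The count ranged from 0 to 49 when single libraries were left out, with 0 without NLR-high replicate 1 or 5, 22 without NLR-low replicate 2 and 49 without NLR-high replicate 6. With only these 2 groups in the fit, 118 genes were called.

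Of the 52 cytosolic ribosomal protein genes, 51 had a lower estimate in NLR-high than in NLR-low neutrophils, with a median log2 difference of -0.46. Of them, 32 were lower when adjusted over the list alone and 1, RPS19, over all genes. RPL4 was 44.0 ± 11.9 against 88.9 ± 16.0 FPKM (list-alone adjusted p = 0.00274), RPS12 26.2 ± 8.45 against 58.7 ± 13.9 and RPS20 35.8 ± 10.5 against 66.9 ± 10.8. The limma set test camera, with its preset correlation between genes, gave the list an adjusted p of 1.03e-24, which became an adjusted p = 0.454 with an estimated correlation. Among stress response genes, the small heat shock protein HSPB1 (0.56 ± 0.34 against 2.45 ± 0.54) and the chaperone HSP90AB1 (9.11 ± 1.78 against 14.7 ± 1.30) were lower over the list alone. That list split into 11 positive and 13 negative estimates, with a camera adjusted p of 0.0435 and an adjusted p = 0.530 with an estimated correlation. BIRC3, an inhibitor of apoptosis induced by NF-kB, was the 1 member of its list of 26 lower over the list alone, at 3.59 ± 1.52 against 8.84 ± 2.02 (camera adjusted p = 0.0122; adjusted p = 0.598 with an estimated correlation).

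Transcripts of antigen-presenting and lymphoid cells were also lower. Of 13 MHC class II genes 12 had negative estimates, with a median of -1.11, and 7 were lower over the list alone. HLA-DPA1 measured 14.3 ± 7.57 FPKM in NLR-high and 40.3 ± 13.8 in NLR-low neutrophils, HLA-DRB1 13.1 ± 5.50 and 29.2 ± 9.50, and the invariant chain CD74 254 ± 89.0 and 392 ± 86.4. All 12 B cell markers had negative estimates (median -1.32), of which the B cell receptor component CD79B passed over the list alone (2.58 ± 0.39 against 11.5 ± 5.11). The mean log2 value of these markers was 0.02 and 0.35 in NLR-low replicates 4 and 5, inside the NLR-high range of -0.43 to 1.28, and 2.19 to 2.89 in the other 4 NLR-low libraries; NLR-high replicates 2 and 5 were the lowest. TCL1A and CD79A measured 1.31 ± 1.04 against 5.73 ± 4.65 and 2.88 ± 1.70 against 11.2 ± 7.65. All 7 plasma cell markers were negative (median -1.52) and 5 were lower over the list alone, among them the antibody chains IGHG1 (6.61 ± 4.44 against 29.4 ± 10.6) and IGHA1 (30.1 ± 20.8 against 138 ± 34.5) and the joining chain JCHAIN (12.5 ± 8.04 against 53.3 ± 12.2). Camera adjusted p-values were 3.09e-07, 4.48e-06 and 3.38e-05 for the 3 lists. They were lost as adjusted p = 0.454, adjusted p = 0.474 and adjusted p = 0.454 with an estimated correlation. In an exact two-sided permutation test of list means, the plasma cell markers were lower by -1.62 in log2 (p = 0.00216, the smallest that 462 splits allow; adjusted p = 0.0216). The B cell markers did not pass that permutation test (permutation p = 0.0714, adjusted p = 0.119).

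Cytotoxic and monocyte transcripts took the same direction. The chemokine receptor CX3CR1 (14.6 ± 4.65 against 32.1 ± 8.38) was the 1 of 16 cytotoxic genes lower over the list alone, and 15 of the 16 had negative estimates. NKG7 and the granzyme GZMB measured 21.5 ± 13.2 against 49.3 ± 22.4 and 5.84 ± 6.10 against 12.3 ± 6.16 FPKM. All 8 NK cell markers were negative (median -0.70, 3 lower over the list alone), as were all 11 monocyte markers (median -0.61), of which CDKN1C passed over the list alone at 10.4 ± 2.03 against 22.2 ± 5.2. MS4A7 measured 17.3 ± 9.10 against 38.3 ± 15.8. In the exact test of list means, the monocyte markers were lower by -0.55 in log2 (permutation p = 0.0173, adjusted p = 0.0722). The NK cell markers were lower by -0.80 (permutation p = 0.0455, adjusted p = 0.0909), and neither list passed. Of 8 dendritic cell markers 7 were negative (median -0.84). Camera adjusted p-values were 0.000256 for the cytotoxic, 0.00175 for the NK cell, 0.00326 for the monocyte and 0.0454 for the dendritic cell list. With an estimated correlation these became adjusted p = 0.482, adjusted p = 0.454, adjusted p = 0.454 and adjusted p = 0.474. The neutrophil markers themselves had a median of 0.16 over 13 genes (camera adjusted p = 0.219).

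Interferon and granule lists were lower as well. All 25 genes of the interferon gamma list had negative estimates (median -0.65) and none passed over the list alone. The tryptophanyl-tRNA synthetase WARS measured 143 ± 70.7 in NLR-high and 365 ± 193 in NLR-low neutrophils, the guanylate-binding protein GBP5 179 ± 85.1 and 575 ± 406, and the high-affinity Fc receptor genes FCGR1A and FCGR1B 15.6 ± 5.31 and 41.8 ± 23.6, and 23.4 ± 7.59 and 46.3 ± 17.2. Of 40 type I interferon genes 38 were negative (median -0.69), with EPSTI1 at 13.5 ± 11.2 and 78.5 ± 94.4 and IFI35 at 41.3 ± 23.7 and 77.8 ± 49.3. All 10 azurophil granule and precursor genes were negative (median -1.10), with RNASE3 at 5.90 ± 5.92 and 18.3 ± 18.3, MS4A3 at 10.2 ± 9.58 and 20.8 ± 14.3, and the defensin DEFA4 at 24.9 ± 22.7 and 64.8 ± 57.0. Of 16 specific granule genes 15 were negative (median -0.71), with haptoglobin, HP, at 5.46 ± 3.67 and 11.2 ± 4.92. Camera adjusted p-values were 1.80e-09, 4.57e-06, 0.000297 and 0.00335 in that order. They became adjusted p = 0.454, adjusted p = 0.598, adjusted p = 0.488 and adjusted p = 0.598 with an estimated correlation. The proliferation list (18 genes, median -0.34) and the replication-dependent histones (8 genes, median -0.48), read here as a sign of RNA without a poly(A) tail, were lower in camera at adjusted p-values of 0.00317 and 0.00578. These became adjusted p = 0.482 and adjusted p = 0.465 with an estimated correlation. The mean of the 5 eosinophil markers was also lower in NLR-high neutrophils, by -0.57 in log2, and did not pass the exact test (permutation p = 0.0216, adjusted p = 0.0722).

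**Figure D2:**
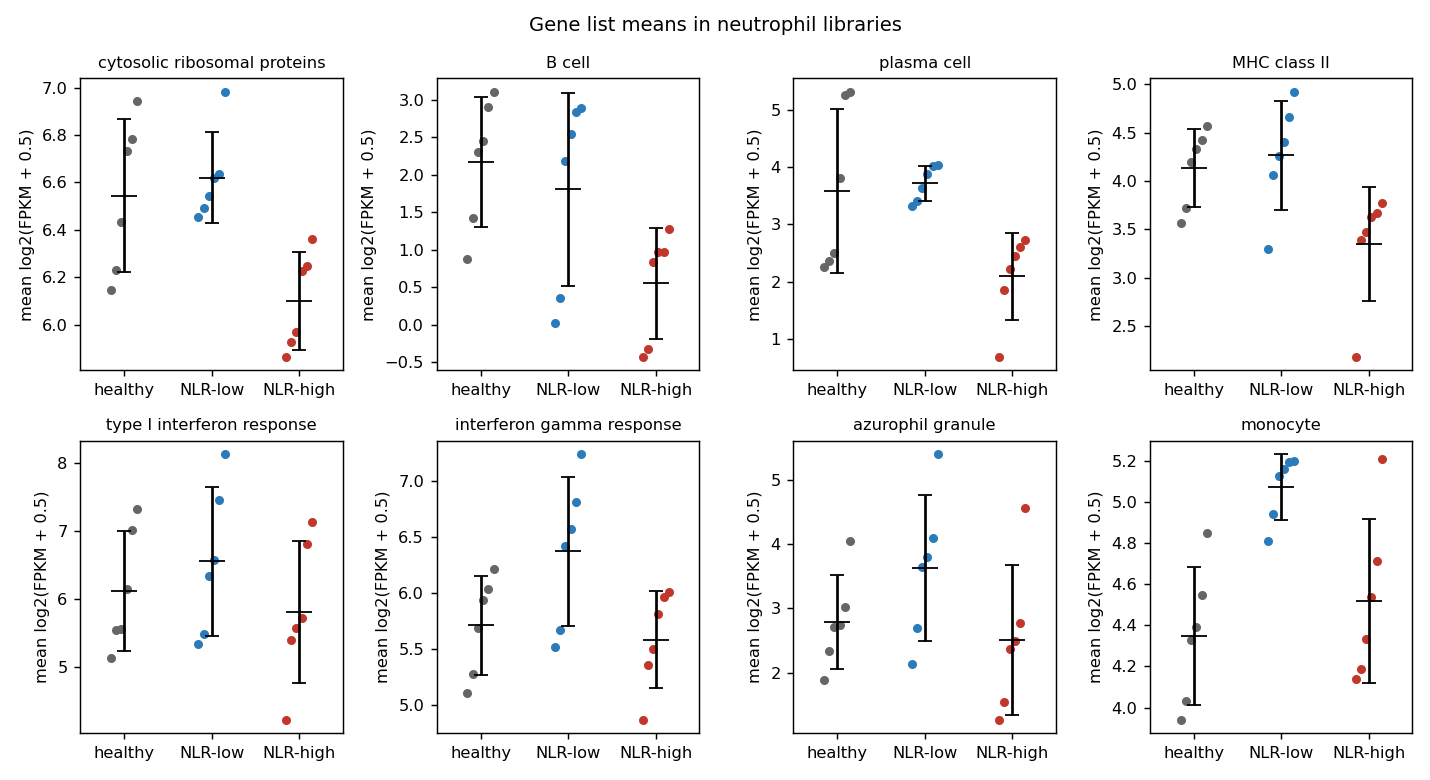
Mean log2(FPKM + 0.5) over the members of 8 gene lists in each neutrophil library, 1 point per library, with the mean and SD of the 6 libraries of each donor group in black. The ribosomal protein, B cell, plasma cell, MHC class II, interferon and granule panels show lower NLR-high than NLR-low means, with list medians between -0.46 and -1.52.

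Complement transcripts in neutrophils are the subject of the series title. No complement list passed camera between NLR-high and NLR-low and no member passed over all genes or over its list alone. The 6 components tested had a median log2 difference of -0.03 (camera adjusted p = 0.714), the 6 regulators -0.13 (0.291) and the 11 receptors 0.08 (0.952); the mean of the receptors was -0.11, opposite in sign to their median. The C1 inhibitor SERPING1 measured 21.8 ± 17.2 FPKM in NLR-high, 57.1 ± 55.4 in NLR-low and 25.5 ± 16.9 in healthy neutrophils (NLR-high against NLR-low -1.26, SE 0.63, limma adjusted p = 0.288). The anaphylatoxin receptor C3AR1 measured 8.67 ± 4.40, 20.6 ± 12.2 and 8.98 ± 3.70 (-1.06, SE 0.42, adjusted p = 0.194), and CD59, which blocks the membrane attack complex, 68.3 ± 14.7, 91.7 ± 26.5 and 62.5 ± 12.2 (-0.41, SE 0.18, adjusted p = 0.239). C3 measured 3.35 ± 2.87 against 4.26 ± 2.53 and the pattern recognition protein FCN1 252 ± 165 against 345 ± 182. The mitochondrial protein C1QBP measured 2.02 ± 0.79 against 3.73 ± 1.07, and the scavenger receptor LRP1 2.37 ± 1.61 against 4.53 ± 2.26. On the other side of 0 lay CD93 at 168 ± 56.2 against 101 ± 30.4 and the integrin ITGAX at 1131 ± 188 against 867 ± 193. The integrins ITGAM and ITGB2, the C5a receptors C5AR1 and C5AR2, CR1, CD46, CD55, C1RL, CFP, CALR and C1R had log2 differences between -0.28 and 0.16. CFD and C4BPA, with differences of -0.05 and -0.14, had SEs of 0.87 and 0.95.

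Some complement genes lay below the filter on low values. Mean FPKM in NLR-high, NLR-low and healthy neutrophils was 0.55, 1.90 and 0.52 for C1QA, 0.12, 0.72 and 0.12 for C1QB, 0.48, 1.18 and 0.33 for C2, and 0.050, 0.25 and 0.056 for CFB. Tested without the filter, over 29512 genes, C1QA differed between NLR-high and NLR-low by -1.04 (SE 0.36), C1QB by -0.90 (SE 0.26) and CFB by -0.46 (SE 0.13). Their limma adjusted p-values were 0.260, 0.194 and 0.194. In lymphocytes the complement components, regulators and receptors had medians of 0.09, 0.20 and 0.13 between NLR-high and NLR-low, and camera adjusted p-values of 0.473, 0.353 and 0.353.

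**Figure D3:**
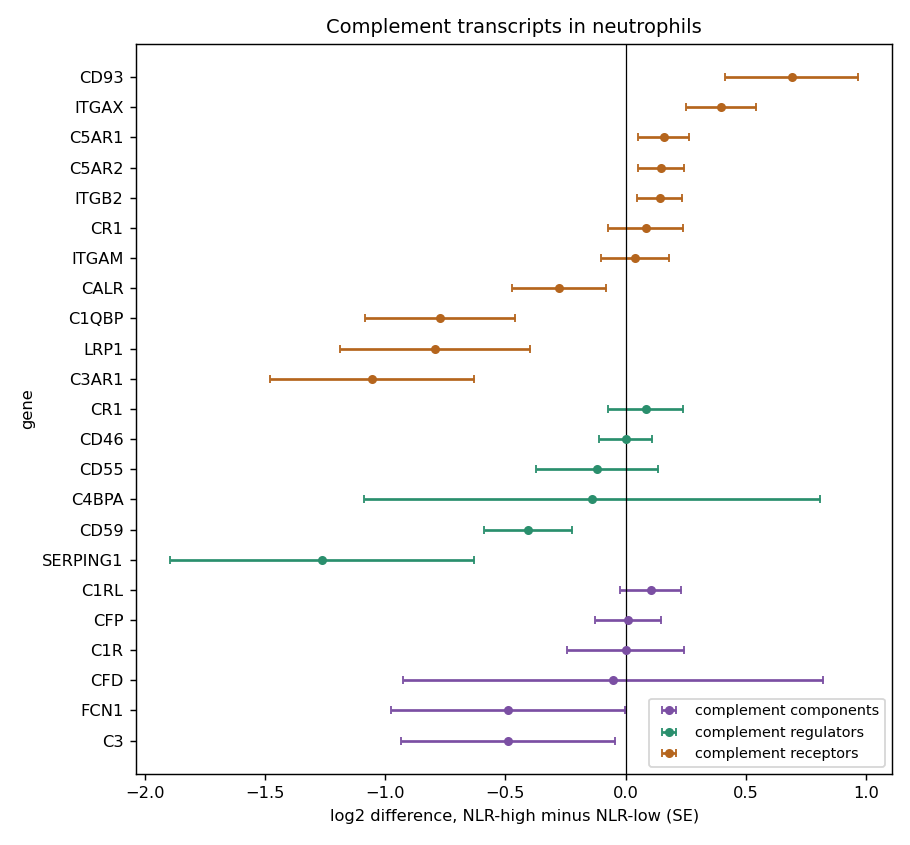
Log2 difference of each tested complement gene between NLR-high and NLR-low neutrophils, with bars of 1 SE; points left of 0 were lower in NLR-high, and colours mark components, regulators and receptors. SERPING1 lies at -1.26 and C3AR1 at -1.06, CD93 at 0.69, and no gene passed the test.

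NLR-high neutrophils were next compared with those of healthy donors. By camera, B cell, plasma cell, MHC class II, ribosomal protein and cytotoxic transcripts were again the lower lists. Chance was not excluded for the number of lists in the random regroupings given below. All 12 B cell markers had negative estimates (median -1.64) and 10 were lower over the list alone, with CD79B at 2.58 ± 0.39 FPKM in NLR-high and 10.4 ± 5.43 in healthy neutrophils, CD79A at 2.88 ± 1.70 and 15.3 ± 11, and BANK1 at 0.97 ± 0.72 and 5.01 ± 2.99. All 7 plasma cell markers were negative (median -1.61, 5 lower over the list alone), with JCHAIN at 12.5 ± 8.04 and 90.6 ± 94.6 and the receptor TNFRSF17 at 0.31 ± 0.27 and 3.4 ± 4.6. Of 52 ribosomal protein genes 50 were negative (median -0.40, 31 lower over the list alone and 0 over all genes), with RPS18 at 42.7 ± 9.65 and 86.7 ± 34.0, RPS12 at 26.2 ± 8.45 and 58.3 ± 24.7, and RPL3 at 63.1 ± 9.45 and 91.1 ± 17.9. All 13 MHC class II genes were negative (median -0.84, 3 lower over the list alone), including HLA-DRB1 at 13.1 ± 5.50 and 27.1 ± 9.51 and the transactivator CIITA at 7.81 ± 2.85 and 12.6 ± 2.84. GZMB, at 5.84 ± 6.10 and 19.5 ± 11.3, was the 1 of 16 cytotoxic genes lower over the list alone (list median -1.10). Camera adjusted p-values of these 5 lists were 1.01e-09, 2.89e-05, 1.32e-21, 3.54e-06 and 5.06e-06. Each became adjusted p = 0.450 with an estimated correlation, and in the exact test of list means the B cell and plasma cell markers had adjusted p-values of 0.0866 and 0.173. The NK cell, proliferation, dendritic cell and type I interferon lists were also lower by camera (adjusted p = 0.00236, 0.0183, 0.0183 and 0.0438), and none passed with an estimated correlation.

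The immediate early list was lower and the hypoxia and glycolysis list higher by camera in the same comparison. MYC (0.65 ± 0.27 against 1.68 ± 0.91 FPKM) and the AP-1 component FOS (2675 ± 2307 against 7075 ± 1875) were the 2 of 25 immediate early genes lower over the list alone, and EGR1 measured 111 ± 175 against 299 ± 249 (list camera adjusted p = 0.00236; adjusted p = 0.558 with an estimated correlation). Of 26 hypoxia and glycolysis genes 23 had positive estimates (median 0.24) and 0 passed over the list alone. The hexokinase HK3 measured 147 ± 29.97 against 94.0 ± 34.7, and the phosphofructokinase PFKP 0.77 ± 0.83 against 1.73 ± 0.80. The Toll-like receptor and inflammasome list (24 of 28 positive, median 0.20) included IL18RAP at 132 ± 46.4 against 75 ± 101. The calcium-binding alarmin S100A11 measured 2344 ± 521 against 1703 ± 292, with 8 of 9 alarmins positive (median 0.28). Camera adjusted p-values for these 3 lists were 0.0156, 0.00974 and 0.0221. Each became adjusted p = 0.558 with an estimated correlation. All 13 mitochondrially encoded transcripts, a measure of RNA quality, had positive estimates (median 0.33, camera adjusted p = 0.0156; adjusted p = 0.602 with an estimated correlation), and all 8 replication-dependent histones negative ones (median -0.32, camera adjusted p = 0.0280; adjusted p = 0.558 with an estimated correlation).

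Limma called 2 genes between NLR-high and healthy neutrophils, ANKRD28 and RN7SL4P, both listed at 0 in every healthy library. At an unadjusted p under 0.05 there were 2062 genes, and 141 genes, or 1.10%, had groups that did not overlap, where chance gives 0.216%. Next to the threshold stood YBX3, a cold shock domain protein, at 112 ± 8.98 against 46.9 ± 23.1 (adjusted p = 0.0537), EMILIN2 at 13.7 ± 2.83 against 7.51 ± 1.39, the calcium pump ATP2B4 at 34.3 ± 3.88 against 19.5 ± 4.86 and the transcription factor RFX2 at 79.2 ± 16.6 against 44.4 ± 7.04. SHMT2 at 1.19 ± 0.46 against 3.79 ± 1.73, LSM7 at 4.41 ± 1.17 against 7.95 ± 1.5 and EVL at 13.2 ± 3.17 against 32.5 ± 12.3 stood on the lower side. Of the complement genes C1QBP, at 2.02 ± 0.79 against 5.21 ± 2.94, was lower over the list alone (adjusted p = 0.0345) and not over all genes (0.132). The complement list medians were 0.15, 0.15 and 0.17 for components, regulators and receptors.

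Between NLR-low and healthy neutrophils, the monocyte, interferon and granule lists were among those higher by camera. Chance was not excluded for the number of list calls in this comparison by the random regroupings given below. Of 11 monocyte markers 10 had positive estimates (median 0.53) and 5 were higher over the list alone. CDKN1C measured 22.2 ± 5.2 FPKM in NLR-low and 10.01 ± 4.17 in healthy neutrophils, lysozyme, LYZ, 1251 ± 440 and 567 ± 364, and MS4A7 38.3 ± 15.8 and 14.9 ± 11.8. The monocyte list had a camera adjusted p of 5.80e-05, an adjusted p = 0.0736 with an estimated correlation and a fry adjusted p of 0.0158. In an exact two-sided permutation test, its mean was higher by 0.72 in log2 (p = 0.00433, adjusted p = 0.0433), a call lost with no filter on low values and without NLR-low replicate 2 and healthy replicate 1. Beside these monocyte markers moved the interferon gamma list, with 24 of 25 estimates positive (median 0.57) and 5 genes higher over the list alone, including FCGR1A at 41.8 ± 23.6 and 11.3 ± 5.36 and WARS at 365 ± 193 and 131 ± 60.3. The inhibitory Fc receptor FCGR2B (39.0 ± 16.1 and 13.3 ± 4.03) was higher over the Fc receptor list alone. Of 16 specific granule genes 15 were positive (median 0.92), and HP, at 11.2 ± 4.92 and 3.56 ± 1.74, passed over the list alone. ARG1, the arginase of neutrophil granules, measured 35.2 ± 7.58 and 18.6 ± 13.8, and MS4A3 of the azurophil list (10 of 10 positive, median 0.85) 20.8 ± 14.3 and 9.37 ± 6.88. Camera adjusted p-values were 4.25e-08 for the interferon gamma, 0.00857 for the Fc receptor, 2.27e-06 for the specific granule and 0.00464 for the azurophil list. With an estimated correlation these became adjusted p = 0.581, adjusted p = 0.581, adjusted p = 0.581 and adjusted p = 0.726.

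The inflammasome list, with AIM2 at 27.2 ± 14.4 and 11 ± 5.94 and CASP5 at 31.8 ± 9.64 and 18.4 ± 6.5, had 21 of 28 positive estimates (camera adjusted p = 0.000561; adjusted p = 0.581 with an estimated correlation). The oxidase subunit CYBB (92.2 ± 30.6 and 50.2 ± 14.1) was among 3 of 8 NADPH oxidase genes higher over the list alone, while camera gave that list an adjusted p of 0.115. The peptide hormone ADM measured 192 ± 50.6 and 108 ± 42.4. By limma 0 genes passed between NLR-low and healthy neutrophils, against 1244 at an unadjusted p under 0.05. The smallest adjusted p was 0.0580, for the glutathione transferase GSTO1 (41.4 ± 9.29 and 22.2 ± 2.62). The transporter ABCC3 (3.93 ± 1.10 and 1.16 ± 0.53), MYOF (3.84 ± 1.13 and 1.20 ± 0.65), the kinase JAK2 (53.9 ± 10.4 and 33.6 ± 5.55) and the small GTPase RRAS (3.68 ± 1.14 and 1.13 ± 0.62) followed. TMEM168 (3.11 ± 0.62 and 4.91 ± 0.40) and the importin IPO13 (2.45 ± 0.43 and 4.32 ± 0.81) lay on the lower side. LRP1 was higher over the complement receptor list alone (1.32, SE 0.40, adjusted p = 0.0405) and not over all genes (0.317). The complement regulators had a median of 0.36 and a camera adjusted p of 0.0578 (0.0477 with only these 2 groups fitted; adjusted p = 0.581 with all groups and an estimated correlation). The type I interferon, extracellular trap, hypoxia and glycolysis, alarmin and MHC class I lists were also higher by camera (adjusted p from 0.00562 to 0.0355), and none passed with an estimated correlation. Of the 13 mitochondrially encoded transcripts, a measure of RNA quality, 12 had positive estimates (median 0.25, camera adjusted p = 0.0141; adjusted p = 0.863 with an estimated correlation).

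In lymphocytes, NLR-high patients had lower interferon, proliferation and respiratory chain lists than NLR-low patients by camera. The random regroupings given below did not exclude chance for the number of list calls here. Of 40 type I interferon genes 36 had negative estimates (median -0.27) and 7 were lower over the list alone, including tetherin, BST2 (26.0 ± 0.92 FPKM in NLR-high and 31.9 ± 3.60 in NLR-low), LY6E (51.2 ± 10.6 and 70.8 ± 8.26), the transcription factor IRF7 (14.5 ± 2.66 and 19.6 ± 2.80) and XAF1 (37.1 ± 9.78 and 65.5 ± 29.7). All 19 interferon gamma genes were negative (median -0.34) and 8 were lower over the list alone, including the guanylate-binding protein GBP1 (18.5 ± 2.87 and 35.0 ± 11.4), the immunoproteasome subunit PSMB8 (58.2 ± 5.63 and 73.8 ± 8.44) and WARS (18.9 ± 4.14 and 34.1 ± 9.78). Of 41 oxidative phosphorylation genes 38 were negative (median -0.14), and the cytochrome oxidase subunits COX6B1 (151 ± 10.7 and 185 ± 8.21) and COX8A (46.2 ± 4.37 and 58.2 ± 8.83) passed over the list alone. All 18 proliferation genes were negative (median -0.35), with the topoisomerase TOP2A (0.83 ± 0.15 and 2.21 ± 1.34) lower over the list alone and ZWINT at 1.12 ± 0.09 and 1.81 ± 0.48. Camera adjusted p-values were 2.53e-16, 3.83e-13, 1.26e-09 and 1.48e-09. Each became adjusted p = 0.213 with an estimated correlation. The heat shock, MHC class I, apoptosis, immediate early, T cell activation and MHC class II lists were also lower by camera (adjusted p from 3.44e-05 to 0.0186), and none passed with an estimated correlation. The replication-dependent histones moved the same way (7 of 8 negative, median -0.18, camera adjusted p = 0.0131; adjusted p = 0.562 with an estimated correlation).

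Plasma cell markers were lower here too (7 of 7 negative, median -0.65), with IGHA1 at 110 ± 69.9 and 209 ± 67.5, and basophil markers higher (6 of 6 positive, median 0.59), with CPA3 at 13.1 ± 3.74 and 7.96 ± 2.52. The naive and memory T cell list had 12 of 13 positive estimates, with the kinase TXK at 29.6 ± 4.85 and 21.2 ± 4.55. Camera adjusted p-values for these 3 lists were 0.000102, 0.00153 and 0.00256. They became adjusted p = 0.218, adjusted p = 0.414 and adjusted p = 0.562 with an estimated correlation, and in the exact test of list means the plasma cell and basophil markers had adjusted p-values of 0.104 and 0.247. Limma called 0 genes, with 1069 at an unadjusted p under 0.05 and 52 whose groups did not overlap (0.372%, where chance gives 0.216%). The smallest p-values on the lower side belonged to the proteasome activator PSME2 (66.2 ± 5.24 and 91.5 ± 6.95), COX6B1, TUSC2 (6.66 ± 0.38 and 8.44 ± 0.52), GBP1 and the histone HIST1H4H (93.7 ± 20.0 and 146 ± 19.1). On the higher side were TTC3 (40.2 ± 2.22 and 32.4 ± 3.14) and the splicing factor CDC40 (19.3 ± 1.48 and 15.4 ± 1.71).

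By camera, lymphocytes of NLR-high patients had a higher basophil list than those of healthy donors. Random regroupings, given below, did not exclude chance for the lists of this comparison. Of the 6 NLR-high libraries 2 had low B cell transcripts. All 6 basophil and mast cell markers had positive estimates (median 0.79) and 5 were higher over the list alone. The IgE receptor chains MS4A2 and FCER1A measured 14.5 ± 5.24 against 5.72 ± 2.90 and 72.7 ± 29.1 against 43.5 ± 22.4 FPKM, and ENPP3 3.74 ± 1.15 against 2.16 ± 1.43. All 12 B cell markers (median -1.20) and all 13 MHC class II genes (median -0.79) had negative estimates, none past the threshold over the list alone. The mean log2 value of the B cell markers was 1.59 and 1.05 in NLR-high replicates 2 and 5, 3.91 to 5.10 in the other 4 NLR-high libraries and 4.30 to 4.80 in healthy ones, and the same replicates were lowest for MHC class II (3.84 and 3.41). CD79A measured 37.2 ± 25.6 against 65.3 ± 12.7, BANK1 13.9 ± 13.2 against 23.4 ± 2.69, HLA-DRA 108 ± 70.8 against 167 ± 20.4 and HLA-DRB1 47.8 ± 23.8 against 66.6 ± 10.1. Camera gave each of these 3 lists an adjusted p of 6.74e-05. With an estimated correlation these became adjusted p = 0.629 for the basophil list and adjusted p = 0.741 for the other 2. In the exact test of list means the basophil markers had p = 0.0368 and the B cell markers p = 0.0736, both with an adjusted p of 0.294. S100A11 measured 64.3 ± 7.34 against 45.0 ± 14.3 and the linker histone HIST1H1C 275 ± 53.8 against 192 ± 48.3. The replication-dependent histones had 7 of 8 positive estimates (median 0.38, camera adjusted p = 0.0046, and adjusted p = 0.741 with an estimated correlation). They were listed as a measure of RNA quality, a reading that was not tested against proliferation. Camera also called the alarmins higher (adjusted p = 0.00448) and the plasma cell markers lower (0.0453), neither of them with an estimated correlation. The mean log2 values of the alarmins and of the monocyte markers were both highest in NLR-high replicate 6 (5.84 and 3.96). Limma called 0 genes, with 1173 at an unadjusted p under 0.05. The smallest p-values belonged to H3F3A (14.3 ± 1.70 and 9.90 ± 1.34), the mitochondrial translocator protein TSPO (37.4 ± 5.94 and 27.7 ± 1.99), TOM1 (16.0 ± 1.59 and 12.2 ± 0.70), AP3M2 (23.6 ± 2.71 and 14.7 ± 3.58), MS4A2 and, on the lower side, SOWAHD (0.66 ± 0.24 and 1.59 ± 0.29).

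Lymphocytes of NLR-low patients compared with healthy donors had higher T cell activation, interferon gamma, respiration and alarmin lists by camera. TSPO rose from 27.7 ± 1.99 to 40.8 ± 1.76 FPKM (log2 difference 0.55, SE 0.09, limma adjusted p = 0.0349; chromosome 22, 43151514 to 43163242). VMP1, a membrane protein of autophagy, rose from 49.5 ± 5.28 to 69.4 ± 5.54 (0.49, SE 0.08, adjusted p = 0.0349; chromosome 17, 59707192 to 59842255). The third gene called, the pseudogene ATP5LP6 (chromosome 17, 76202644 to 76202796), was listed at 0 in 25 of the 36 libraries, including all NLR-low lymphocyte libraries, and ranged from 2.60 to 13.9 in the 11 others. Without genes listed at 0 in a whole group no call remained, TSPO and VMP1 both standing at an adjusted p of 0.0522; over the settings that kept all libraries or left out the doubted one TSPO ranged from 0.00278 to 0.114 and VMP1 from 0.0172 to 0.114. The regulatory T cell factor FOXP3 (5.65 ± 1.65 against 2.66 ± 0.54), the costimulatory receptor TNFRSF4 (11.2 ± 2.39 against 6.01 ± 1.79) and the IL-2 receptor chain IL2RA (8.76 ± 4.02 against 4.72 ± 1.07) were the 3 of 19 T cell activation genes higher over the list alone. Of 19 interferon gamma genes 18 were positive and 7 were higher over the list alone, including SOCS3 (34.7 ± 18.4 against 11.1 ± 4.90), WARS (34.1 ± 9.78 against 18.9 ± 5.39) and PSMB10 (108 ± 12.1 against 84.4 ± 10.8).

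Of 41 oxidative phosphorylation genes 36 were positive and 8 were higher over the list alone, COX6B1 among them (185 ± 8.21 against 152 ± 8.35). Of 9 alarmins 4 were higher over the list alone, including S100A6 (161 ± 18.6 against 111 ± 13.9), HMGB2 (55.5 ± 12 against 35.4 ± 6.24) and S100A11 (80.4 ± 20.0 against 45.0 ± 14.3). Camera adjusted p-values for the T cell activation, interferon gamma, oxidative phosphorylation and alarmin lists were 0.000269, 1.19e-07, 3.22e-08 and 0.000407. Each became adjusted p = 0.270 with an estimated correlation, while fry gave 0.0372 for the first and 0.0499 for the other 3. The glycolytic enzymes GAPDH (278 ± 34.2 against 206 ± 28.0), LDHA (73.0 ± 13.2 against 54.6 ± 6.94) and PGAM1 (7.27 ± 0.69 against 5.17 ± 1.06), the death receptor FAS (22.0 ± 7.76 against 11.5 ± 3.53) and the early response factor KLF6 (130 ± 21.8 against 94.4 ± 14.4) were each higher over their list alone. Replication-dependent histones moved with these lists (8 of 8 positive, median 0.55, camera adjusted p = 2.04e-06; adjusted p = 0.270 with an estimated correlation), with HIST1H1C at 311 ± 46.2 against 192 ± 48.3. Camera also called higher the type I interferon, immediate early, MHC class I, proliferation, apoptosis, heat shock, hypoxia and glycolysis, NF-kB, T cell, T helper and cytotoxic lists (adjusted p from 2.12e-07 to 0.0495), none of them with an estimated correlation.

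All 12 B cell markers had negative estimates in this comparison (median -1.15, camera adjusted p = 0.000886; adjusted p = 0.585 with an estimated correlation), with CD22 at 41.9 ± 38.0 against 66.9 ± 17.4 and MS4A1 at 57.0 ± 45.3 against 87.2 ± 15.3. Here NLR-low replicates 4 and 5 stood apart, with B cell means of 1.13 and 1.09 in log2 against 4.02 to 5.03 in the other 4 NLR-low libraries and 4.30 to 4.80 in healthy ones (exact test of list means, adjusted p = 0.552). The naive and memory T cell list was lower (11 of 13 negative, median -0.26, camera adjusted p = 0.00158; adjusted p = 0.521 with an estimated correlation), with the homing receptor CCR7 at 81.5 ± 32.0 against 123 ± 46.8. Limma called 3 genes, 2 higher and 1 lower, with 1910 at an unadjusted p under 0.05 and 131 whose groups did not overlap (0.938%, where chance gives 0.216%). Below the threshold followed DUSP5 (7.76 ± 2.10 against 3.20 ± 0.96), NOL3 (2.02 ± 0.89 against 0.66 ± 0.25), ZNF175 (3.53 ± 0.37 against 5.12 ± 0.63) and CDC40 (15.4 ± 1.71 against 20.7 ± 2.21). The count was 0 without NLR-low replicate 3, 4, 5 or 6 or healthy replicate 1, and 17 without NLR-low replicate 2. After median-ratio scaling or quantile normalization 0 genes were higher and 1 lower.

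Whether a difference between donor groups itself differed between the cell types was tested as an interaction. For NLR-high against NLR-low, limma called 15 of 16073 genes, 2 with a more positive and 13 with a more negative difference in neutrophils. The 2 are ANKRD28 and RN7SL4P, and 1 of the 13 is ATP5LP6, all listed at 0 in whole groups. Among the 15, RPS19 differed by -0.98 (SE 0.19, adjusted p = 0.0301) and TMPO by -1.33 (SE 0.22, adjusted p = 0.00431). DNMT1 differed by -0.94 (SE 0.20) and PLIN2 by -1.35 (SE 0.28), both with an adjusted p of 0.0457. For NLR-high against healthy donors 4 genes were called, ANKRD28 and RN7SL4P among them. For NLR-low against healthy donors 1 was called, ATP5LP6, which is listed at 0 in whole groups. With the donor as a block, which pairs the cell types, the first 2 counts were 38 and 10. The 15 became 5 with a pseudocount of 1, 3 with no filter on low values, 4 under quantile normalization and 32 with array weights.

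The type I interferon list was lower by camera in NLR-high than in NLR-low libraries of both cell types. Its mean was followed from one cell type to the other within donors. Over the 18 donors, deviations from the group means in neutrophils and lymphocytes correlated with Pearson's r = 0.81 (permutation p = 3e-05, adjusted p = 0.00111 over 37 lists) and Spearman's rho = 0.84 (permutation p = 0.00011). Without the 2 donors farthest from the median r was 0.73, and within NLR-high, NLR-low and healthy donors it was 0.92, 0.95 and 0.45. Of the 37 lists, 9 passed an adjusted p of 0.05, among them the plasma cell (r = 0.91), MHC class II (0.74), B cell (0.78) and monocyte (0.68) lists. Within healthy donors r was 0.20 for both the MHC class II and the B cell list, against 0.90 and 0.93 for B cells within NLR-high and NLR-low donors, each of which included 2 donors with low B cell values.

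**Figure D4:**
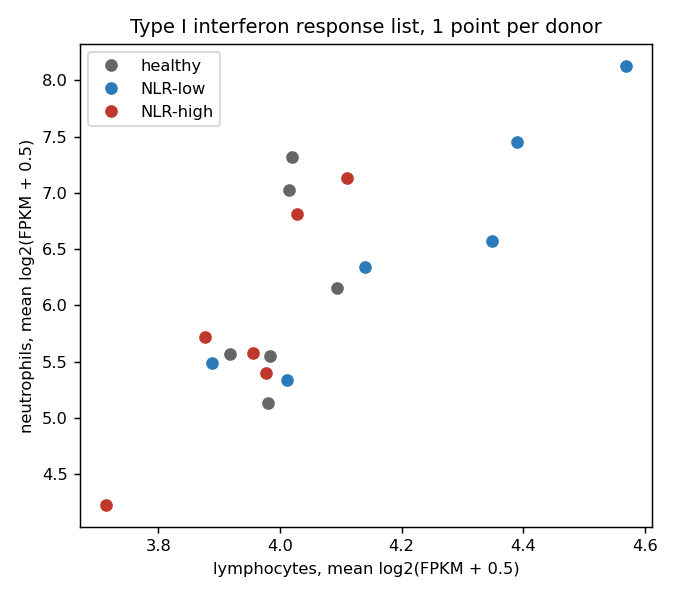
Mean log2(FPKM + 0.5) of the type I interferon list in the lymphocytes (horizontal axis) and neutrophils (vertical axis) of each donor, 1 point per donor, coloured by donor group. Donors with higher values in lymphocytes had higher values in neutrophils, with r = 0.80 over the values as plotted and r = 0.81 after removal of the group means.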

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

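The tests of the locus listed at 0 and the count without genes listed at 0 were chosen only after the result was seen, as were the use of the leave-one-out range in the B cell covariate test and of the median itself in the scaling test, and the other tests were planned or written before their results.

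A single locus gave the largest difference between donor groups: ANKRD28 and RN7SL4P were above 0 in the 6 NLR-high neutrophil libraries and listed at 0 in the other 30, so that the difference between NLR-high and NLR-low was larger in neutrophils than in lymphocytes by 5.19 for ANKRD28 and 7.93 for RN7SL4P (and by the same 5.19 and 7.93 against healthy donors), values that depend on the pseudocount and are no measured fold. A failed estimate in the authors' quantification may account for it, because EEF1A1, which every cell uses, is listed at 0 in all 18 lymphocyte libraries, although this shows only that a 0 in the table can be a failed estimate. A first version of that test counted genes listed at 0 in a whole group and above 0 in another group of the same cell type: there were 3, and the highest of 99 regroupings also gave 3. That tie met the bound set against a failed estimate and also the bound of 3 set against a gene switched on in NLR-high neutrophils, but not by more than its spread, so it is read as deciding nothing, and the EEF1A1 test replaced it after it had been run. For a gene switched on in NLR-high neutrophils, 0 of the other 30 libraries hold a value above 0 for ANKRD28 that could be compared, so the explanations cannot be told apart.

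The ribosomal protein, MHC class II, B cell, plasma cell and cytotoxic lists were lower in NLR-high than in NLR-low neutrophils, with a ribosomal protein median of -0.46. Lymphocyte RNA in the neutrophil libraries is a candidate source. A mixed lymphocyte preparation would have to bring its T cell transcripts too. The T cell markers averaged 1.65 FPKM in neutrophils against 91.4 in lymphocytes. Subtracting the share they allow (medians of 0.0954% in NLR-high and 0.243% in NLR-low) left the ribosomal median at -0.43 and the B cell median at -1.31. That subtraction covers only RNA with the composition of the donor's lymphocyte library. B cells, plasma cells or NK cells left behind without T cells would not be removed by it. The B cell means of NLR-low, 1.80 in log2 in neutrophils and 3.37 in lymphocytes, lie closer than that share allows. A scaling factor per library would move all genes alike, and is argued against because the median of all tested genes was 0.05. The ribosomal median was -0.50 under median-ratio scaling and -0.54 under quantile normalization. With the median of all genes already near 0, this rescaling could move it little and adds little. RNA of B cells and plasma cells left in the neutrophils after their isolation was tested with the B cell score as a covariate. The ribosomal median was then -0.33 (camera adjusted p = 2.48e-17), past the bound of -0.30 set beforehand, but from -0.37 to -0.27 with single libraries left out, so the bound is not passed by more than its spread. None of these 18 fits came within 0.1 of 0, the bound set for such RNA as the cause. The MHC class II median went from -1.11 to -0.55 (camera adjusted p = 0.00406), the plasma cell median from -1.52 to -1.06 (0.000396) and the cytotoxic median from -0.96 to -0.29 (0.0647). Such RNA is therefore not excluded for any of the 5 lists, as the cause or a part of it. The B cell list cannot be tested against its own score. Monocyte markers were lower in NLR-high neutrophils too, by -0.55 in log2 (permutation p = 0.0173, adjusted p = 0.0722). Monocyte RNA was not tested as a source of these lists. RNA quality was not tested as a source. RPPH1 and RMRP took a mean of 2.80% of FPKM in NLR-high and 5.53% in NLR-low neutrophils. The histone list mean was lower in NLR-high by -0.46 in log2 (exact permutation p = 0.0455, adjusted p = 0.0909). That of the mitochondrially encoded transcripts differed by 0.08 (permutation p = 0.669). The split of donors by NLR, which was not tested against other differences between the patients, stays open as an explanation. Donors were grouped by the blood ratio of neutrophils to lymphocytes itself. By this design, a change within neutrophils therefore cannot be told apart from fewer lymphoid cells left in NLR-high preparations. This holds for the ribosomal protein, MHC class II and cytotoxic lists. The B cell and plasma cell lists mark lymphoid cells. Over donors, their neutrophil means went with the lymphocyte means (r = 0.78 and 0.91). Within healthy donors r was 0.20 for B cells. NLR-high replicates 2 and 5 and NLR-low replicates 4 and 5 were lowest for B cell markers in both cell types. These values go with lymphoid RNA in the neutrophil libraries for those lists.

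By camera with its preset correlation, the interferon lists were lower in NLR-high than in NLR-low patients in both cell types. The spread between donors does not establish this difference. In neutrophils the type I list means overlapped, at 4.23 to 7.13 in NLR-high and 5.34 to 8.13 in NLR-low. Fry gave that list an adjusted p of 0.427. Both cell types came from the same donors, so the second is not an independent observation. A single donor that decides the sign of the difference is argued against. Without any 1 of the 12 donors the type I interferon median stayed at or below -0.18 (-0.95 to -0.38 in neutrophils, -0.31 to -0.18 in lymphocytes). The size of the difference in neutrophils did depend on single donors, at -0.69 with all donors and -0.38 at its weakest. A state of the donor shared by both cell types may underlie it, in that the donors' deviations from their group means went together (r = 0.81, permutation p = 3.00e-05). That link lies within groups and does not show that NLR is what differs.

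Random regroupings of the libraries were used to see whether chance can be excluded, with the real grouping among 100 in each case. For NLR-high against NLR-low neutrophils 1 grouping, the real one, gave as many as 5 genes (highest other 3). The real one alone also gave as many as 16 lists (highest other 15, median 8) and a ribosomal median of the size of 0.46 (highest other 0.41). Of these 5 genes, ANKRD28 and RN7SL4P are 1 locus listed at 0 outside the NLR-high neutrophils. The ribosomal list was the only list whose median was regrouped, and these shares do not allow for the number of tests run. Chance is therefore not taken as excluded. Without genes listed at 0 in a whole group, 2 gave as many as the real 2 genes (highest other 2). For NLR-high against healthy neutrophils 2 gave as many as 2 genes. These are ANKRD28 and RN7SL4P, and without genes listed at 0 in a whole group the count is 0. In this comparison 1 regrouping called 52, which points to a structure of the samples whose cause was not tested. There, 17 gave as many as 15 lists (highest other 21) and 5 a ribosomal median as large as 0.40 (highest other 0.46), so chance is not excluded for these. It is not excluded either for the lists of NLR-low against healthy neutrophils (36 gave as many as 12, highest other 25), or of lymphocytes for NLR-high against NLR-low (30 gave as many as 14, highest other 23), NLR-high against healthy (84 gave as many as 6, highest other 23) and NLR-low against healthy donors (11 gave as many as 18, highest other 20).

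Counts of 0 genes were found in NLR-low against healthy neutrophils and in NLR-high against NLR-low and against healthy lymphocytes. There all 100 groupings gave as many, with highest others of 2, 2 and 1. No other outcome was possible for a count of 0, so these regroupings decide nothing. For NLR-low against healthy lymphocytes 3 gave as many as 3 genes (highest other 4). Of the 3 genes 1 is ATP5LP6, and without genes listed at 0 the count is 0. No regrouping was run for that count, and any grouping would reach 0, so it decides nothing. Chance is not taken as excluded here either. Regrouping donors with both libraries together, 1 gave as many as the 15 interaction genes for NLR-high against NLR-low (highest other 6), 2 as many as 4 for NLR-high against healthy (highest other 69, again a structure of untested cause) and 11 as many as 1 for NLR-low against healthy (highest other 2, chance not excluded). When the 2 libraries of a random set of donors were exchanged, 1 gave as many as the 14638 genes between cell types (highest other 12494).

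Differences between NLR-high and NLR-low that differed between the cell types by the interaction test were, as neutrophil minus lymphocyte, -0.98 for RPS19, -1.33 for TMPO, -0.94 for DNMT1, -1.35 for PLIN2, -1.33 for EVL and -1.53 for FUOM. ATP5LP6, listed at 0 in 25 libraries, gave -2.75 there and 3.83 for NLR-low against healthy donors.

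Of 553 groups of 6 libraries examined, in 35 the highest or lowest library stood apart, its gap to the nearest other divided by the range of the group exceeding Dixon's 95% critical value for 6 samples, where chance alone gives 27.65. NLR-high neutrophil replicate 5 was the library in 5 of them: lowest for CD93 (ratio 0.658), CIITA (0.650), CYBB (0.664), FCGR1B (0.676) and the MHC class II list (0.761). Other NLR-high neutrophil libraries stood highest for AIM2 (0.635), C4BPA (0.666), LYZ (0.730) and RPS12 (0.704) and lowest for RRAS (0.692). NLR-low neutrophil replicate 4 stood highest for C4BPA (0.765), replicate 5 highest for CD46 (0.764) and lowest for the T cell activation list (0.638), and replicate 3 highest for RPS20 (0.723), the ribosomal protein list (0.657) and the basophil list (0.762). Healthy neutrophil libraries stood highest for EMILIN2 (0.644), ITGAX (0.699) and the complement component list (0.636) and lowest for TMEM168 (0.787).

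In lymphocytes, NLR-high replicate 3 stood lowest for GAPDH (0.672), LDHA (0.789), PGAM1 (0.737) and the oxidative phosphorylation list (0.658). NLR-high replicate 6 stood lowest for ATP5LP6 (0.672), at 0, and highest for the complement regulator list (0.658), and replicate 4 lowest for the plasma cell list (0.646). NLR-low replicate 3 stood highest for COX6B1 (0.720), HIST1H1C (0.707) and the immediate early list (0.682), and replicate 5 lowest for SOWAHD (0.724). Healthy libraries stood highest for LY6E (0.769) and VMP1 (0.722) and lowest for XAF1 (0.664) and the oxidative phosphorylation list (0.754).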

How the results depend on the processing

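The fits without genes listed at 0 in a whole group, without doubted libraries and without genes 4 times higher in lymphocytes were chosen after seeing the data; the other settings were fixed before, and the ribosomal protein median was added to the leave-one-out fits after its result was seen. Leaving 1 library out apart, 270 of the comparison values did not move (counts within 1.5 times, medians with the same sign and side of the threshold), 55 counts moved, 2 medians changed sign and 1 passed the threshold only there. Of the single-gene and ribosomal values 2008 kept sign and side, 30 passed the threshold only there, 22 only in the first fit and 12 changed sign. Where not stated otherwise, the cause was not tested. The counts-based tests set down for a table of counts were not run, because the table holds FPKM.

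For NLR-high against NLR-low neutrophils the 5 genes became 8 with a filter at 5 FPKM, 118 with the 2 groups fitted alone, 283 at an adjusted p under 0.10, 2 without genes listed at 0 (ANKRD28 and RN7SL4P leave by construction, and IGHV3-21 goes to an adjusted p of 0.0551), 18 without NLR-low replicate 2 and healthy replicate 1, and 2 without genes 4 times higher in lymphocytes. In that last fit 0 of the 3 lower genes remain: RPS19 and TMPO leave by construction, and IGHV3-21 is at an adjusted p of 0.0517. The 2 genes against healthy neutrophils became 89 at an adjusted p under 0.10, 0 without genes listed at 0 and 4 without genes higher in lymphocytes. The 0 genes of NLR-low against healthy neutrophils became 1 with no filter, with a filter at 5 FPKM, with the 2 groups fitted alone, at an adjusted p under 0.10 and without the doubted libraries. In lymphocytes, the 0 genes of NLR-high against NLR-low became 1 without NLR-high replicate 6, and the 3 genes of NLR-low against healthy became 0 with no filter, 1 under median-ratio scaling, 1 under quantile normalization, 26 at an adjusted p under 0.10, 1 with a log2 change of at least 1, 0 without genes listed at 0 (ATP5LP6 leaves by construction, and TSPO and VMP1 go to 0.0522) and 1 without that NLR-high library.

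The list calls in neutrophils (16, 15 and 12 for NLR-high against NLR-low, NLR-high against healthy and NLR-low against healthy) and lymphocytes (14, 6 and 18) became 0 in each of the 6 comparisons with an estimated correlation. With fry they became 0, 0 and 1 in neutrophils and 0, 0 and 7 in lymphocytes. The number of marker list means past the exact test, 1 for NLR-high against NLR-low neutrophils, became 2 with no filter, 3 with a filter at 5 FPKM, 5 at an adjusted p under 0.10 and 2 without the doubted libraries. For NLR-high against healthy neutrophils 0 became 1 at an adjusted p under 0.10, for NLR-low against healthy neutrophils 1 became 0 with no filter and 0 without the doubted libraries, and for NLR-low against healthy lymphocytes 0 became 1 with a filter at 5 FPKM and 1 at an adjusted p under 0.10. The 15 interaction genes for NLR-high against NLR-low became 5 with a pseudocount of 1, 3 with no filter, 4 under quantile normalization, 32 with array weights and 37 at an adjusted p under 0.10. The 4 against healthy donors became 17 with array weights and 12 at an adjusted p under 0.10, and the 1 for NLR-low became 0 with array weights.

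Complement differences between NLR-high and NLR-low neutrophils near 0 changed sign: C1R to 2.26e-05 and 7.84e-05 with pseudocounts of 0.1 and 1 and 0.0740 under quantile normalization; CFP to -0.0289 under median-ratio scaling, -0.0373 under quantile normalization and -0.0103 with array weights; CD46 to -0.0393, -0.0871 and -0.0135 under these 3 and -0.00535 without the doubted libraries; C4BPA to 0.0195 and ITGAM to -0.0209 under quantile normalization. Between NLR-high and healthy neutrophils the medians of complement components and complement regulators became -0.0109 and -0.00691 with no filter. The regulator median of NLR-low against healthy neutrophils, 0.36, passed the threshold with the 2 groups fitted alone (0.36, camera adjusted p = 0.0477).

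Across NLR groups the replicate numbers are different donors and do not pair: over the 6 comparisons, same-numbered libraries correlated best with each other in 0 to 2 of 6 pairs, with r from -0.186 to 0.202 (2 of 6 for NLR-high against NLR-low lymphocytes). In neutrophils the replicate block gave 2 genes in place of 5 for NLR-high against NLR-low and 5 in place of 2 for NLR-high against healthy donors, with other counts within a cell type changed by at most 2. With the donor as a block across cell types, the interaction counts were 38 in place of 15 and 10 in place of 4.

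Leaving out 1 library at a time, counts of genes ranged from 0 to 49 (NLR-high against NLR-low), 0 to 4 (NLR-high against healthy) and 0 to 2 (NLR-low against healthy) in neutrophils and 0 to 1, 0 to 1 and 0 to 17 in lymphocytes. The low counts without an NLR-high neutrophil library arise in part by construction, since ANKRD28 and RN7SL4P then miss the filter of 6 libraries. Against healthy donors the count was 0 without NLR-high replicate 1, 4, 5 or 6. Medians of complement components, regulators and receptors ranged from -0.19 to 0.0435, -0.35 to 0.00071 and 0.0033 to 0.15 for NLR-high against NLR-low, 0.10 to 0.25, 0.10 to 0.24 and 0.10 to 0.21 against healthy, and 0.17 to 0.51, 0.22 to 0.40 and -0.00061 to 0.11 for NLR-low against healthy. The ribosomal protein median ranged from -0.50 to -0.40, -0.47 to -0.33 and -0.0116 to 0.15 in the same order. The approximate relative depth was lower in neutrophil libraries (7.73 at the lowest against 20.4 in lymphocytes), but a scaling of the libraries to each other would also move it. How depth bears on low genes was not tested. Complement genes at 1 FPKM or more in fewer than 6 libraries were left out by the filter.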

Other observations

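Of the links between cell types only that of the type I interferon list had a prediction written beforehand; the other 36 lists, the lists described below and the genes picked without the filter were chosen after values had been seen.

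Within donors, list means of the neutrophil and lymphocyte libraries went together beyond interferon. Some of these lists mark B cells and plasma cells, whose RNA in the neutrophil libraries was not excluded. Their links therefore need not be changes of the neutrophils. After removal of the group means, 31 of 37 lists had a positive correlation over the 18 donors. Plasma cell markers gave r = 0.91 (permutation p = 0.00024, adjusted p = 0.00444, rho = 0.80 with permutation p = 0.00119, r = 0.89 without the 2 farthest donors). The heat shock list gave r = 0.70 (permutation p = 0.0013, adjusted p = 0.0120, rho = 0.71 with permutation p = 0.0018, r = 0.61 without the 2 farthest) and the glucocorticoid list r = 0.71 (permutation p = 0.00257, adjusted p = 0.0183, rho = 0.64 with permutation p = 0.00688, r = 0.49 without the 2 farthest). For MHC class II genes r = 0.74 (permutation p = 0.00123, adjusted p = 0.0120) became 0.42 without the 2 farthest donors, and for proliferation r = 0.71 (permutation p = 0.00296, adjusted p = 0.0183) became 0.39, so both rest in part on those donors.

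Several neutrophil functions did not pass between NLR-high and NLR-low. The NADPH oxidase list had a median of 0.04 over 8 genes, the chemotaxis and adhesion receptors 0.11 over 17, gelatinase and secretory granules 0.09 over 13, the extracellular trap list -0.27 over 9 and the glucocorticoid list 0.09 over 15. Camera adjusted p-values lay between 0.138 for the extracellular trap list and 0.952.

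Complement genes near the limit of detection, picked after their values were seen, had positive estimates for NLR-low against healthy neutrophils without the filter and none passed: 1.04 (SE 0.36) for C1QA, 0.86 (SE 0.26) for C1QB, 0.92 (SE 0.36) for C2 and 0.43 (SE 0.13) for CFB, with limma adjusted p-values of 0.561, 0.498, 0.602 and 0.506. The monocyte markers were higher by 0.72 in NLR-low neutrophils. Whether the same cells carry both was not tested.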
